A study of Homo sapiens with 12 samples.

How the data were processed

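RNA was measured in HEK293 cells, an established human embryonic kidney line, in 4 groups of 3 biological replicates, 12 arrays in all. MED12 is a subunit of the kinase module of Mediator, the complex that links transcription factors to RNA polymerase II. Per the labels, cells were transfected by lipofection 24 hours after plating and harvested 48 hours later, and living, GFP-positive cells were collected by a 20 minute flow sort per sample. The groups received nuclear GFP alone (the control), full-length MED12, MED12 without its C-terminal PQL and Opa domains (hereafter the PQL/Opa-deleted construct), or a plasmid that makes a short hairpin RNA (shRNA) against MED12. Both MED12 constructs carried the same nuclear GFP tag and were in the same vector as the control; the hairpin was in another GFP vector, and the labels list 0 groups with a control hairpin. RNA was amplified, labelled with biotin and measured on 1-colour arrays.

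The deposited values are on a log2 scale, with 1 value per row and array; a row is a transcript cluster, the summary of the probes of a gene or a group of neighbouring genes. The submitters' processing notes name Partek, RMA and the genome build hg18. The version of Partek, the probe set level, the background option and any filter are not given in the sources used here. Which part of MED12 its row's probes cover is also not given. The deposited values were used as they stand, with no further normalization, filter or offset, and 0 columns of values were left out. The arrays had medians between 3.39 and 3.51. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.23.

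The file held 22011 rows. The annotation table gave 1 gene symbol for 14432 rows, several symbols for 2408 and no symbol for 5171. Entrez identifiers of 14404 of the rows with 1 symbol were found in a current RefSeq gene table, and 0 symbols had to be renamed. Rows with several symbols are called by their row number, since no gene can be assigned to them. No positions are given, because the annotation available for gene names is on another genome build than the one the submitters' processing notes name.

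A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, 8 residual and 3.52 prior degrees of freedom). Each construct and the hairpin were compared with GFP, which are the comparisons the series design names, and full-length MED12 was compared with the PQL/Opa-deleted construct. The limma tests were two-sided, with Benjamini-Hochberg adjustment over all rows and a threshold of 0.05. A moderated F test asked which rows differed among the 4 groups. Every adjusted p given comes from limma unless another source is named. Those of single rows set a difference against the spread between the biological replicates of this experiment. Those of camera, the gene list test described below, compare the members of a list with other genes. With its preset correlation, a small camera p does not measure the spread between replicates. For a single value, an exact permutation test of 3 against 3 arrays cannot go below 0.1, so each row is tested with limma's model, which takes its spread from all 4 groups and moderates it towards that of the other rows.

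The labels number the replicates but do not say what a number marks. Deviations from the group means of same-numbered arrays correlated over 0.1 in all 3 pairs for full-length MED12 with GFP (0.101 to 0.229) and for the PQL/Opa-deleted construct with GFP (0.149 to 0.472), and not in all pairs for the other groups. A fit with the number as a block is therefore given beside those comparisons where it changes a call.

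Sets of genes were tested with limma's camera (preset correlation between genes of 0.01) over 30 lists, each with at least 3 measured members and 1 row per gene, the row with the highest mean over the 12 arrays, against a background of 14233 genes. The lists covered Mediator and RNA polymerase II, signalling pathways, stress and interferon responses, the cell cycle, metabolism, RNA interference, and markers of this and other cell types. Beside each call stands camera with a correlation estimated per list. The fry test of limma, which asks whether the members move, on balance, 1 way, was run as well. Its p-values are printed for some of the heat shock and interferon calls only. For the other calls no fry value is shown, and the number of lists past with fry in each planned comparison is given with the alternatives. Members are counted over all rows and again adjusted over the list alone. A list score per array is the mean over the members of the log2 value minus the mean of the GFP arrays.

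The groups, comparisons, tests, threshold, lists and the rule for naming genes were set before the data were examined. By that rule MED12 and MED12L, its paralogue, are named in every comparison. In each comparison with GFP the rule then names up to 10 rows per direction with the largest change among those that carried 1 symbol, passed, and had groups that did not overlap. Where fewer than 10 passed, up to 5 more per direction with the smallest unadjusted p are named as not having passed. For the comparison of the constructs the number was 5 per direction, and for each list up to 4 members with the smallest p are named. Any other gene is said to have been chosen after its values were seen.

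Log2 fold changes of the comparisons with GFP were correlated across rows and set beside 1000 simulations of unchanged groups that share their controls. The pipeline was tested on simulated data with 200 of the 22011 rows changed in the hairpin comparison. It recovered 4.48% of the rows changed by 0.6, 82.1% of those changed by 1.5 and 93.9% of those changed by 2.5 on the log2 scale, with 4 false calls, and made 0 calls in an unchanged comparison. A simulated change of 0.5 in a whole list gave an adjusted p of 7.10e-15 with camera, and 0 of the 29 other lists were called. Both simulations drew independent noise for each row and array, with no correlation between genes and no structure among arrays. Their counts of false calls therefore do not measure those in the deposited data.

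Alternatives fixed beforehand were a fit with the replicate number as a block, a fit with only the compared groups, subtraction of each array's median, quantile normalization, removal of the dimmest 25% of rows, limma's array weights, no moderation of the spread, a prior spread that follows intensity, a threshold of 0.1, an added fold threshold of 1.5, the mean of all rows of a gene, and leaving out each array in turn. Alternatives chosen after seeing the data were cyclic loess between arrays, leaving out the 3 arrays with the narrowest spread of values, leaving out the 4 arrays numbered 1, counting rows with several symbols as list members, and the comparisons of the hairpin arrays with each MED12 construct. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.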

Results

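Gene expression in sorted, GFP-positive HEK293 cells was measured on 12 arrays 48 hours after transfection. The 4 groups, each with 3 biological replicates, were GFP alone, full-length MED12, MED12 without its PQL and Opa domains, and an shRNA against MED12. The comparisons ask how the transcripts of these cells differ when MED12 is overexpressed, when a shortened form of it is overexpressed, and when it is targeted by RNA interference. The arrays differed in how widely their log2 values spread. The standard deviation was 1.34 in shRNA replicate 1, 1.40 in GFP replicate 1 and 1.45 in PQL/Opa deletion replicate 1, the 3 narrowest arrays. It was 1.47 in shRNA replicate 3, 1.51 in full-length replicate 1 and 1.56 to 1.60 in the others.

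The MED12 transcript (row 3980758) stood far above the control in both overexpression groups and below it in every shRNA array. Its log2 value was 4.41 ± 0.34 (SD, n = 3) with GFP, with single arrays at 4.03, 4.56 and 4.66. It was 10.68 ± 0.06 (SD, n = 3) with full-length MED12, from 10.63 to 10.75, a 77.0-fold rise (limma, adjusted p = 3.67e-08, higher in 3 of 3 arrays). With the PQL/Opa-deleted construct it was 8.92 ± 0.32 (SD, n = 3), from 8.62 to 9.25, a 22.7-fold rise (limma, adjusted p = 1.54e-06, higher in 3 of 3 arrays). Which part of MED12 the probes cover is not given, and probes in the deleted domains would not read the shortened construct, so its value is not a measure of amount alone. In the shRNA arrays it was 3.67 ± 0.06 (SD, n = 3), from 3.63 to 3.74. That is a log2 fold change of -0.75 ± 0.20 (SE), which did not pass over all rows (limma, adjusted p = 0.730) and passed when adjusted over the list alone, the 7 genes of the Mediator kinase module. All 3 shRNA arrays lay below all 3 GFP arrays. MED12L, the paralogue of MED12, did not pass in any comparison with GFP, with log2 fold changes of -0.07 (full-length), 0.13 (PQL/Opa-deleted) and -0.02 (shRNA). The first is above 0 without GFP replicate 1 or full-length replicate 1. The last is above 0 in 2 of the 12 fits that left out 1 array, at most 0.13, without shRNA replicate 2.

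**Figure D1:**
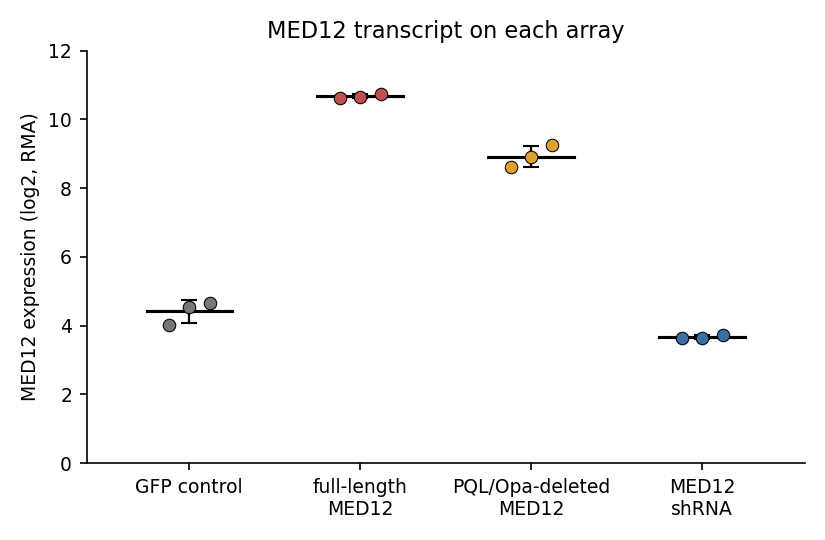
Log2 value of the MED12 row (vertical axis) in each of the 12 arrays by group, with points for arrays, a line for the group mean and bars for the SD (n = 3). Means are 4.41 with GFP, 10.68 with full-length MED12, 8.92 with the PQL/Opa-deleted construct and 3.67 with the shRNA.

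With full-length MED12, heat shock genes rose as a group. These genes encode chaperones and co-chaperones that refold or hold damaged proteins. Of the 16 measured members 14 had a positive log2 fold change, with a mean of 0.67 and a median of 0.71 (limma's camera, adjusted p = 8.11e-19; adjusted p = 0.0120 with an estimated correlation; adjusted p = 0.00566 with fry). The list score was 0.67 ± 0.06 (SD, n = 3) with full-length MED12 against 0.00 ± 0.25 (SD, n = 3) with GFP, where the lowest array, at -0.28, was the narrow replicate 1. No member passed over all rows (0 of 16 with limma, 8 at an unadjusted p under 0.05), and 7 passed when adjusted over the list alone. Among those 7, DNAJB1, a co-chaperone of the HSPA family, had a log2 fold change of 2.22 ± 0.30 (SE; limma, adjusted p = 0.0664 over all rows), from 3.72 ± 0.27 to 5.93 ± 0.38 (SD, n = 3). With the replicate number as a block DNAJB1 passed (limma, adjusted p = 0.0160), as it did without shRNA replicate 2 (adjusted p = 0.0175). HSPH1, a nucleotide exchange factor for HSPA chaperones, had 1.30 ± 0.27 (SE), HSPA1L had 1.16 ± 0.21 and SERPINH1, the collagen chaperone, had 0.77 ± 0.16.

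Over all 22011 rows, 3 rose with full-length MED12 and 0 fell (limma). They were MED12 and a pair of rows annotated to more than 1 gene, at least 1 of them in the heat shock list. Row 2363784 rose 5.18-fold, from 4.45 ± 0.19 to 6.83 ± 0.13 (SD, n = 3; limma, adjusted p = 1.31e-04). Row 3391149 rose from 1.81 ± 0.21 to 4.14 ± 0.25 (SD, n = 3; limma, adjusted p = 0.00321). Its GFP mean lies at the 6.35th percentile of rows and is not shown to be above background, so the size of its rise is uncertain. At an unadjusted p under 0.05 there were 617 rows, where chance alone gives 1101, and groups did not overlap in 7.72% of rows, where chance gives 10%. Among rows that did not pass, ZFAND2A, a heat- and arsenite-inducible zinc finger gene, had a log2 fold change of 0.98. The lowest p-values on the negative side were those of TRMT44 at -0.66, FNDC9 at -1.10, CEBPA-DT at -1.38, LRRC18 at -0.64 and THAP5 at -0.61, none of which passed.

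A further 5 lists were called higher with full-length MED12 by camera, none with an estimated correlation. Their means were small except that of the Mediator kinase module, which came largely from MED12. Interferon-stimulated genes had a mean of 0.19, with 21 of 28 members above 0 (camera, adjusted p = 2.53e-04; adjusted p = 0.313 with an estimated correlation). ISG15 had the smallest p of the list, at 0.70. Immediate early serum response genes had a mean of 0.15, with 22 of 27 above 0 (camera, adjusted p = 3.06e-04; adjusted p = 0.313 with an estimated correlation). Of these, EGR1, a growth factor-induced transcription factor, had 0.66 and was the 1 member past when adjusted over the list alone; DUSP1 had 0.61. Targets of ATF4, the transcription factor of the amino acid stress response, had a mean of 0.16 and 23 of 27 above 0 (camera, adjusted p = 9.41e-04; adjusted p = 0.313 with an estimated correlation), with DDIT4 at 0.81. Nuclear-encoded oxidative phosphorylation genes had a mean of 0.16 and 36 of 47 above 0 (camera, adjusted p = 1.31e-04; adjusted p = 0.506 with an estimated correlation), with NDUFB10 at 0.55. In the Mediator kinase module the mean was 0.94 and the median 0.11 (camera, adjusted p = 0.00195; adjusted p = 0.313 with an estimated correlation), and MED12 itself was the 1 member past over all rows and when adjusted over the list alone. CDK8, the kinase of the module, had 0.17. With the replicate number as a block, RNA polymerase II subunits, with a mean of 0.19, were called as well (camera, adjusted p = 0.0385; 0.0874 without the block). Apart from MED12, 0 members of these 5 lists passed over all rows (limma; at an unadjusted p under 0.05 the lists held 4, 4, 1, 3 and 1 members in the order given). Adjusted over the list alone, 0 members of the interferon, ATF4 and oxidative phosphorylation lists passed. Without the narrow GFP replicate 1 the mean of the oxidative phosphorylation genes was 0.038 (camera, adjusted p = 0.814), that of the ATF4 targets 0.11 (adjusted p = 0.0974) and that of the kinase module 0.78 (adjusted p = 0.159), so these calls were lost. The mean of the immediate early genes was 0.098 without GFP replicate 2 (camera, adjusted p = 0.0387). The module also lost its call without full-length replicate 2 (0.85; adjusted p = 0.179).

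With the PQL/Opa-deleted construct, interferon-stimulated genes rose as a group. These genes are switched on by interferons and by sensing of foreign nucleic acid, and many encode antiviral proteins. Of the 28 measured members 26 had a positive log2 fold change, with a mean of 0.37 and a median of 0.28 (limma's camera, adjusted p = 1.38e-14; adjusted p = 0.0432 with an estimated correlation; adjusted p = 0.0480 with fry). The list score was 0.37 ± 0.04 (SD, n = 3) against 0.00 ± 0.07 (SD, n = 3) with GFP. No member passed over all rows (0 of 28 with limma, 7 at an unadjusted p under 0.05), and 5 passed when adjusted over the list alone. IFIT3, which binds other IFIT proteins, had a log2 fold change of 1.39 ± 0.27 (SE; limma, adjusted p = 0.860). RSAD2, which encodes the antiviral enzyme viperin, had 1.05 ± 0.22 (SE), IFIT2 had 0.94 ± 0.25 and IFI44 had 0.91 ± 0.16 (limma, adjusted p = 0.598).

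MED12 was the 1 row of 22011 that passed with this construct, and it was higher (limma; 0 rows fell). With the replicate number as a block 2 rows passed, the other being row 2686794, which has no symbol, at -1.35 ± 0.14 (SE; limma, adjusted p = 0.0493). At an unadjusted p under 0.05 there were 761 rows, where chance alone gives 1101, and groups did not overlap in 7.92% of rows, where chance gives 10%. Among rows that did not pass, UBB, a ubiquitin gene, had a log2 fold change of 0.75 and NUP50, a nuclear pore gene, had 0.71. On the negative side stood KRTAP3-1 at -0.75, ND6, a mitochondrially encoded subunit of complex I, at -0.81, OR56A3 at -1.03, BET1 at -0.63 and PCNP at -0.50.

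Camera called another 5 lists higher with the PQL/Opa-deleted construct, none of them with an estimated correlation. Heat shock genes had a mean of 0.23, with 13 of 16 above 0 (camera, adjusted p = 0.00131; adjusted p = 0.321 with an estimated correlation). HSPA8, the constitutive cytosolic chaperone, had 0.62, while HSP90AA1, the inducible cytosolic HSP90 gene, had -0.51. Without the narrow GFP replicate 1 the heat shock mean was 0.09 (camera, adjusted p = 0.476), and without PQL/Opa deletion replicate 3 it was 0.20 (adjusted p = 0.0828). Oxidative phosphorylation genes had a mean of 0.17 and 36 of 47 above 0 (camera, adjusted p = 6.61e-05; adjusted p = 0.650 with an estimated correlation), with ATP5PB at 0.74. Cytosolic ribosomal protein genes had 0.23 and 18 of 26 above 0 (camera, adjusted p = 0.0204; adjusted p = 0.321 with an estimated correlation), with RPS14 at 0.93. Hypoxia and glycolysis genes had 0.09 and 20 of 28 above 0 (camera, adjusted p = 0.0204; adjusted p = 0.321 with an estimated correlation), with ENO1, a glycolytic enzyme, at 0.91. In the Mediator kinase module the mean of 0.62 came from MED12, and the median was -0.0015, of the opposite sign to the mean and the test (camera, adjusted p = 0.0317; adjusted p = 0.674 with an estimated correlation; adjusted p = 0.123 with the replicate number as a block). In these 5 lists 0 members other than MED12 passed over all rows or when adjusted over the list alone (limma; 3, 4, 3, 2 and 1 members, in the order given, had an unadjusted p under 0.05). None of the 5 calls held without GFP replicate 1, where the mean was 0.054 for oxidative phosphorylation, 0.15 for ribosomal proteins, 0.045 for hypoxia and glycolysis and 0.45 for the module (camera, adjusted p from 0.476 to 0.797). The last 3 were also lost without PQL/Opa deletion replicate 2 (0.25, 0.086 and 0.58) or replicate 3 (0.22, 0.051 and 0.50). The hypoxia and glycolysis mean was 0.14 without GFP replicate 3 or PQL/Opa deletion replicate 1, and the module was lost without full-length replicate 2 or shRNA replicate 1 (0.62 in both).

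In the shRNA arrays, interferon-stimulated genes rose strongly. The 13 genes that rose over all rows included IFIT1, IFIT2 and IFIT3, which encode RNA-binding antiviral proteins, RSAD2, IFI44, the antiviral TRIM22, IFITM1, a membrane protein that blocks virus entry, and OAS2, a sensor of double-stranded RNA. IFIT2 was 6.21-fold above GFP, at 6.60 ± 0.51 against 3.97 ± 0.28 (SD, n = 3; limma, adjusted p = 0.00220). RSAD2 was 6.04-fold above it, at 6.28 ± 0.28 against 3.69 ± 0.27 (SD, n = 3; limma, adjusted p = 0.00117), and IFI44 was 5.60-fold above it, at 5.72 ± 0.23 against 3.24 ± 0.14 (SD, n = 3; limma, adjusted p = 1.12e-04). In each of these 13 genes all 3 shRNA arrays lay above all 3 GFP arrays.

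All 28 measured interferon-stimulated genes had a positive log2 fold change in the shRNA arrays, with a mean of 1.19 and a median of 1.05 (limma's camera, adjusted p = 1.09e-55; adjusted p = 4.17e-04 with an estimated correlation; adjusted p = 1.51e-05 with fry). Over all rows 8 of them passed, and 20 passed when adjusted over the list alone. The list score was 1.19 ± 0.20 (SD, n = 3), with 1.01, 1.40 and 1.17 in replicates 1, 2 and 3; replicate 2 had the widest spread of values of the 3. The other members that passed were IFIT3 at 2.38 ± 0.27 (SE), TRIM22 at 2.25 ± 0.28, IFIT1 at 2.24 ± 0.27, IFITM1 at 1.80 ± 0.22 and OAS2 at 1.45 ± 0.20. MX1, an antiviral GTPase, did not pass over all rows, with 1.20 (limma, adjusted p = 0.0762), nor did RIGI, a sensor of viral RNA, with 1.74 (limma, adjusted p = 0.0884). The other 5 genes that rose were outside the list: NT5C3A, a nucleotidase, at 1.81, PARP14 at 1.59, NMI, which binds MYC and STAT proteins, at 1.58, SAMD9 at 1.49 and ERAP2, a peptidase that trims antigens, at 0.96 ± 0.15 (SE; limma, adjusted p = 0.0470). With GFP, NMI was at 1.94 ± 0.27 and TRIM22 at 2.34 ± 0.23 (SD, n = 3), the 7.81th and 14.6th percentiles of rows. OAS2 was at 2.60 ± 0.25, the 20.6th percentile, and ERAP2 at 2.67 ± 0.11 (SD, n = 3). None of these genes is shown to be above background with GFP, so the sizes of their rises are uncertain.

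**Figure D2:**
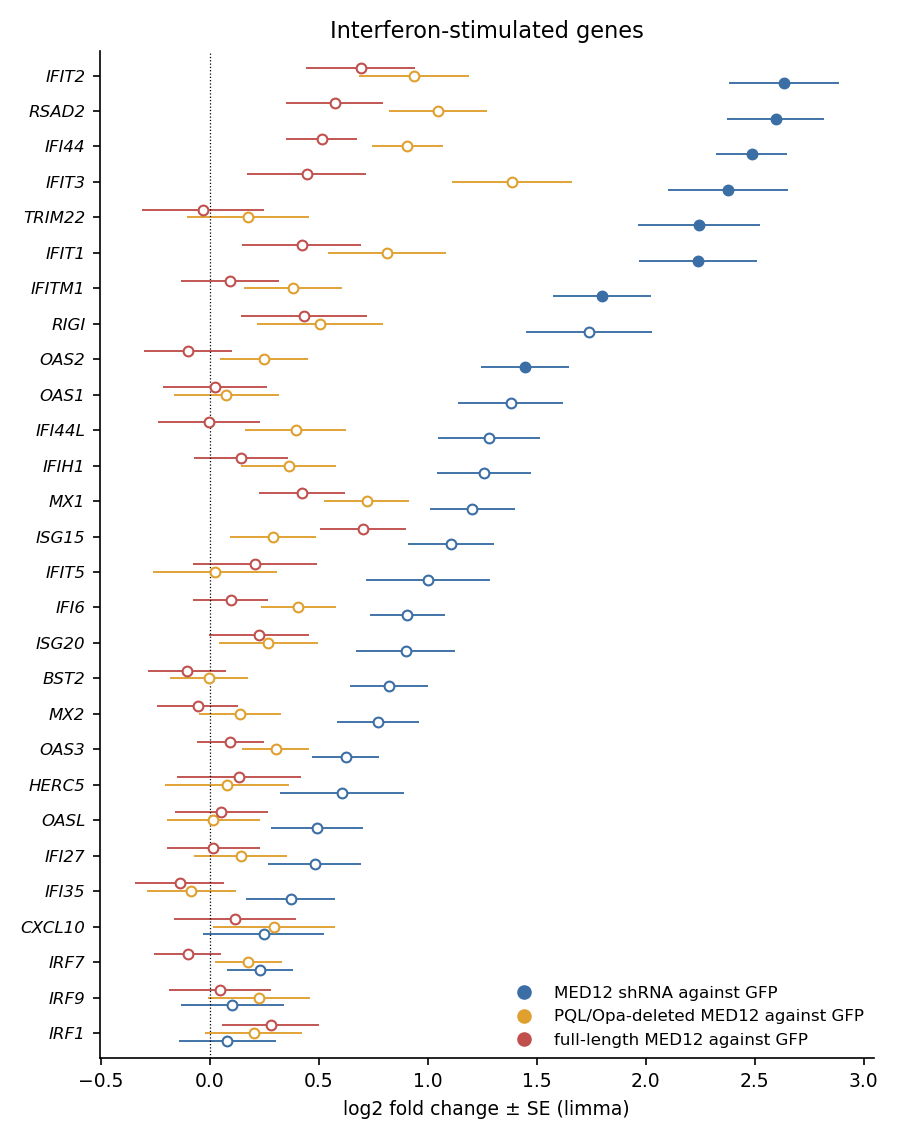
Log2 fold change against GFP (horizontal axis, ± SE from limma) of each measured interferon-stimulated gene for the shRNA, the PQL/Opa-deleted construct and full-length MED12; filled points have an adjusted p under 0.05 over all rows and open points do not. All 28 members lie above 0 with the shRNA, 26 with the PQL/Opa-deleted construct and 21 with full-length MED12.

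Of the 22011 rows, 15 passed with the shRNA, 13 higher and 2 lower (limma). Both lower rows are annotated to more than 1 gene, at least 1 of them in the heat shock list: row 2902707 had -1.39 ± 0.18 (SE; limma, adjusted p = 0.0166) and row 2363784 had -1.11 ± 0.17 (SE; limma, adjusted p = 0.0448). Among rows that did not pass, SKP1, a subunit of ubiquitin ligases, had -1.08 (it passed without full-length replicate 3; limma, adjusted p = 0.0303), UTP11 had -0.86, LSMEM1 -0.84, MTDH -0.79 and ZNF654 -0.78. At an unadjusted p under 0.05 there were 1110 rows, where chance alone gives 1101, and groups did not overlap in 8.56% of rows, where chance gives 10%. The count of 15 was 5 without GFP replicate 2, 8 without GFP replicate 3, 4 in a fit of the shRNA and GFP arrays alone, 23 after quantile normalization and 5702 with array weights, which gave shRNA replicate 3 a weight of 8.77. RSAD2, IFI44, IFIT2, NMI and SAMD9 passed in each of the 12 fits that left out 1 array. The call was lost in 12 of these fits for ERAP2 (log2 fold changes from 0.90 to 1.05), in 11 for row 2363784 (from -1.25 to -1.01), in 9 for PARP14 (from 1.34 to 1.78) and in 9 for OAS2 (from 1.23 to 1.59). It was lost in 4 for TRIM22 and row 2902707, in 2 for IFIT1 and IFITM1, and in 1, without GFP replicate 2, for IFIT3 and NT5C3A.

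Heat shock genes were lower as a group in the shRNA arrays by camera, with a mean of -0.32, a median of -0.33 and 13 of 16 members below 0 (limma's camera, adjusted p = 4.32e-04; adjusted p = 0.226 with an estimated correlation). With fry the heat shock list did not pass with the shRNA (adjusted p = 0.401). No member passed over all rows or when adjusted over the list alone (0 of 16 with limma, 5 at an unadjusted p under 0.05). HSPH1 had a log2 fold change of -0.82, HSPA1L -0.71, HSPA4L -0.59 and HSP90AA1 -0.49. The score was -0.32 ± 0.28 (SD, n = 3) and lay lowest, at -0.61, in shRNA replicate 1, the array with the narrowest spread of values. It was -0.31 in replicate 3 and -0.04 in replicate 2, whose values spread most widely. The mean was -0.17 without shRNA replicate 1 (camera, adjusted p = 0.0728), -0.46 without GFP replicate 1, also narrow, and -0.31 without the 3 narrow arrays (camera, adjusted p = 2.47e-04).

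**Figure D3:**
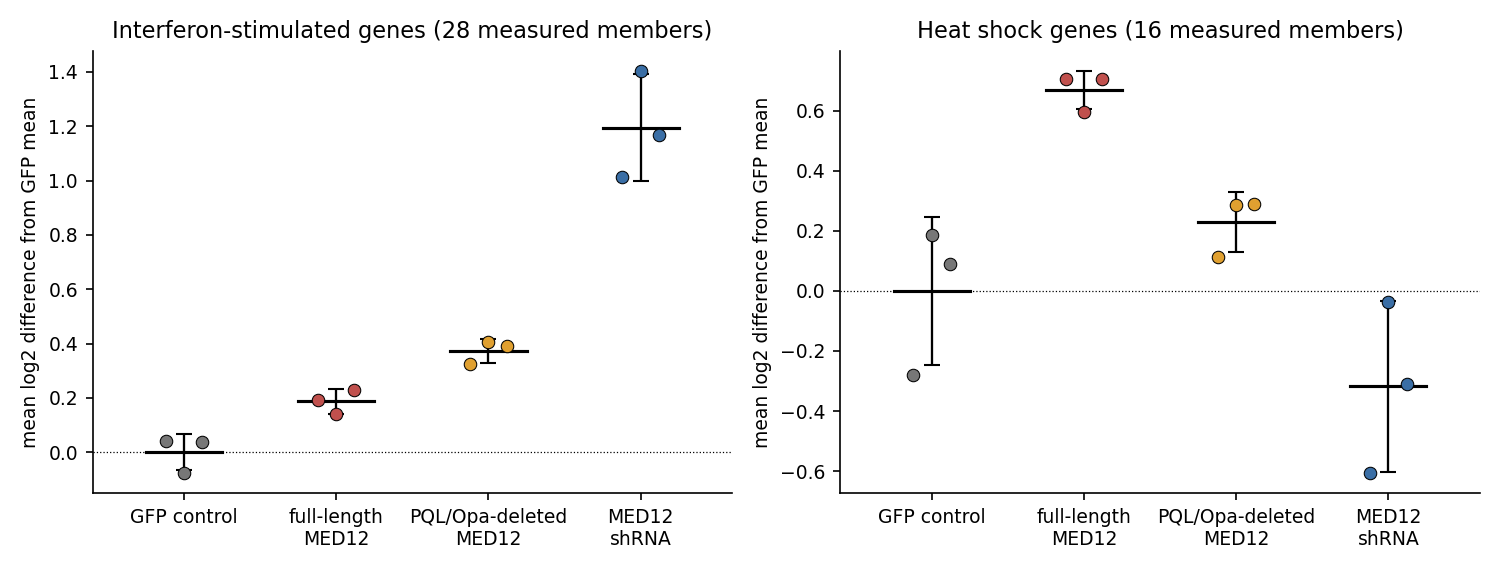
Mean log2 value of the list members relative to the mean of the GFP arrays (vertical axis) in each array by group, for 28 interferon-stimulated genes and 16 heat shock genes, with points for arrays, a line for the group mean and bars for the SD (n = 3). The interferon score is 1.01 to 1.40 in the shRNA arrays, and the heat shock score is 0.60 to 0.71 with full-length MED12 and -0.61 to -0.04 with the shRNA.

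Camera called 5 more lists with the shRNA, none with an estimated correlation. Hedgehog pathway genes had a mean of 0.23, with 10 of 11 above 0 (camera, adjusted p = 0.0109; adjusted p = 0.589 with an estimated correlation), and NKX2-2, a transcription factor downstream of the pathway, had 0.78. The Mediator kinase module had a mean of -0.24, with 6 of 7 members below 0 (camera, adjusted p = 0.0406; adjusted p = 0.589 with an estimated correlation). CCNC, its cyclin, had -0.44, CDK8 had -0.33, and MED12 was the 1 member past when adjusted over the list alone. Genes of G2 and mitosis had -0.13 and 23 of 31 below 0 (camera, adjusted p = 0.0406; adjusted p = 0.799 with an estimated correlation), with CENPE and HMMR both at -0.72. Replication-dependent histones had -0.15 and 24 of 41 below 0 (camera, adjusted p = 0.0474; adjusted p = 0.226 with an estimated correlation), with H2AC16 at -1.50. Genes typical of HEK293 cells had -0.15 and 7 of 10 below 0 (camera, adjusted p = 0.0492; adjusted p = 0.226 with an estimated correlation), and NEFM, a neurofilament gene, had -0.60 and was the 1 member past when adjusted over the list alone. In these 5 lists 0 members passed over all rows (limma; at an unadjusted p under 0.05 there were 3, 1, 2, 1 and 1 members in the order given), and 0 of the Hedgehog, mitosis and histone genes passed when adjusted over the list alone. None of the 5 calls held without shRNA replicate 1, the narrowest array, where the means were 0.16, -0.13, -0.0083, -0.12 and -0.13 in the order given (camera, adjusted p from 0.0728 to 0.856), or without GFP replicate 3, where they were 0.21, -0.12, -0.019, -0.15 and -0.12. Without GFP replicate 2 the last 4 were lost, with -0.19, -0.057, -0.13 and -0.14. In the other direction the mitosis mean was -0.31 without GFP replicate 1 and -0.28 without shRNA replicate 2, and that of the kinase module was -0.40 without GFP replicate 1, all past the threshold. Without shRNA replicate 3 the mitosis and HEK293 calls were lost (-0.10 and -0.13), and without shRNA replicate 2 the histone call (-0.11). The histone and HEK293 calls, near the threshold, were also lost without full-length replicate 2 or PQL/Opa deletion replicate 1, and the HEK293 call without full-length replicate 3 or PQL/Opa deletion replicate 3, with the means as given.

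Full-length MED12 and the PQL/Opa-deleted construct were compared directly to ask whether the deleted domains change the response. The MED12 row was 3.38-fold higher with the full-length construct, a log2 difference of 1.76 ± 0.20 (SE; limma, adjusted p = 0.0421), and was the 1 row that passed. Heat shock genes were higher with full-length MED12 by a mean of 0.44, with 14 of 16 members above 0 (limma's camera, adjusted p = 2.85e-11; adjusted p = 0.0607 with an estimated correlation). With fry the heat shock list did not pass between the constructs (adjusted p = 0.242). Over all rows 0 of its members passed with limma, and 7 had an unadjusted p under 0.05. When adjusted over the list alone 5 passed, among them DNAJB1 at 1.58 ± 0.30 (SE), HSPH1 at 0.83 ± 0.27, HSPA1L at 0.68 ± 0.21 and HSP90AA1 at 0.57 ± 0.18. Against GFP, HSP90AA1 had 0.07 with full-length MED12 and -0.51 with the PQL/Opa-deleted construct, so its difference came mainly from the latter. Interferon-stimulated genes were lower with full-length MED12, with a mean of -0.19 and 23 of 28 below 0 (camera, adjusted p = 3.73e-06; adjusted p = 0.166 with an estimated correlation), and IFIT3 had -0.94.

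In the same comparison immediate early genes had a mean of 0.12, with 19 of 27 above 0 (camera, adjusted p = 0.00537; adjusted p = 0.612 with an estimated correlation), and EGR1 had 0.53. Replication-dependent histones had -0.12, with 28 of 41 below 0 (camera, adjusted p = 0.00697; adjusted p = 0.0767 with an estimated correlation), and H4C1 had -0.91. The Mediator kinase module had 0.32, with 5 of 7 above 0 (camera, adjusted p = 0.0219; adjusted p = 0.686 with an estimated correlation) and MED12 the 1 member past over all rows and when adjusted over the list alone; MED12L had -0.20. Of the interferon, immediate early and histone lists, 0 members passed over all rows or when adjusted over the list alone (limma; 2, 1 and 3 had an unadjusted p under 0.05). Among other rows that did not pass, KRTAP3-1 had 0.77, GPRASP2 0.59 and MINPP1 0.56, and PRPH2 had -0.70, GABARAP, an autophagy gene, -0.90, BTN3A2 -0.54 and TMSB10, an actin-binding protein gene, -0.73. At an unadjusted p under 0.05 there were 419 rows, where chance alone gives 1101, and groups did not overlap in 6.91% of rows, where chance gives 10%. The kinase module call was lost without full-length replicate 2 (0.23; camera, adjusted p = 0.568) or PQL/Opa deletion replicate 1 (0.16; adjusted p = 0.446). The immediate early call was lost without full-length replicate 3 (0.095) or PQL/Opa deletion replicate 2 (0.072), and the histone call without full-length replicate 1 (-0.085) or PQL/Opa deletion replicate 2 (-0.10). The adjusted p of MED12 stayed under the threshold in 3 of the 12 fits that left out 1 array.

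**Figure D4:**
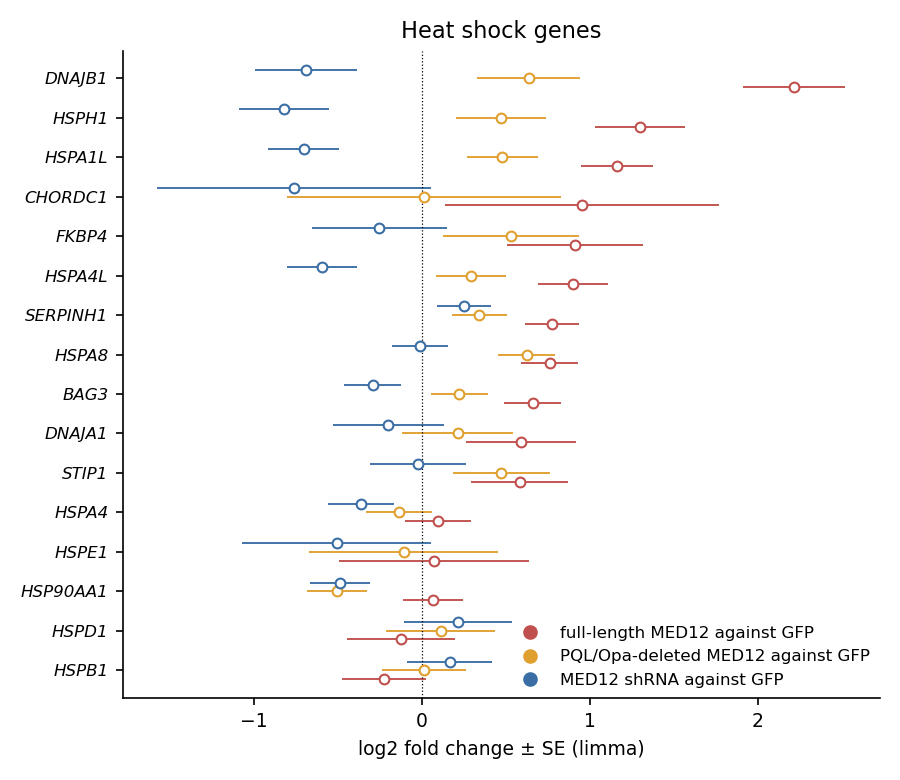
Log2 fold change against GFP (horizontal axis, ± SE from limma) of each measured heat shock gene for the shRNA, the PQL/Opa-deleted construct and full-length MED12; all points are open because no member has an adjusted p under 0.05 over all rows. Of the 16 members 14 lie above 0 with full-length MED12 and 13 lie below 0 with the shRNA.

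Camera called 6 lists with full-length MED12, 6 with the PQL/Opa-deleted construct, 7 with the shRNA and 5 between the constructs. Each of these counts includes the Mediator kinase module, which holds MED12, the gene transfected or targeted, so the design bears on that call. With an estimated correlation 1 call held in each comparison with GFP, heat shock genes for full-length MED12 and interferon-stimulated genes for the other 2, and 0 held between the constructs.

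Over the 4 groups together, 19 rows differed by the moderated F test (limma), of which 15 carried 1 symbol; 1017 had an unadjusted p under 0.05. The F test called 15 rows that had also passed in a comparison with GFP and 4 that had not: DNAJB1 and ZFAND2A (limma, adjusted p = 0.0121 for both), HSPA1L (limma, adjusted p = 0.0223) and row 2902725, annotated to more than 1 gene, at least 1 of them in the heat shock list. The count was 10 without GFP replicate 2, 9 without full-length replicate 2, 9 without shRNA replicate 1 and 5 without shRNA replicate 3.

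The log2 fold changes of the comparisons with GFP were correlated across all 22011 rows, which are not independent replicates. Pearson's r was 0.599 (Spearman's rho 0.564) between full-length MED12 and the PQL/Opa-deleted construct, 0.288 (0.235) between full-length MED12 and the shRNA, and 0.344 (0.297) between the PQL/Opa-deleted construct and the shRNA. Leaving out 1 array gave from 0.480 to 0.749 for the first. The second was 0.115 without shRNA replicate 2, 0.451 without GFP replicate 1 and 0.503 without GFP replicate 3. The third was 0.189 without PQL/Opa deletion replicate 1, 0.196 without shRNA replicate 2 and 0.521 without GFP replicate 3. The jackknife standard errors were 0.255, 0.349 and 0.330. Unchanged groups sharing their controls gave median r values of 0.523, 0.545 and 0.542 in 1000 simulations, with 95% of values from -0.16 to 0.877, -0.17 to 0.886 and -0.15 to 0.878. All 3 observed values lay inside these ranges, and those with the shRNA lay below the simulated medians. With 3 shared control arrays, too few to divide, part or all of each correlation may come from the controls. MED12, the transfected gene, was the 1 row higher with both constructs, which the design fixes. Row 2363784 was the 1 row higher with full-length MED12 and lower with the shRNA, and its shRNA call was lost in 11 of the 12 fits that left out 1 array.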

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

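The tests of array spread, of hairpin plasmid against MED12 level and of construct amount, and the comparisons of the shRNA arrays with each MED12 construct, were chosen, with their bounds, only after the results were seen; the counts over other splits of the arrays were planned.

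A difference between 2 treated groups, tested directly, marked the results in this part. Between full-length MED12 and the PQL/Opa-deleted construct the MED12 row differed by 1.76 (limma, adjusted p = 0.0421, higher in 3 of 3 arrays). List means differed by 0.44 for heat shock genes, -0.19 for interferon-stimulated genes, 0.12 for immediate early genes, -0.12 for replication-dependent histones and 0.32 for the Mediator kinase module, each past the threshold with camera and none with an estimated correlation. The kinase module holds MED12, which both arms transfect, and its difference rests largely on that row. Whether the difference of the MED12 row is one of amount or of probed sequence is not known. Between the shRNA arrays and full-length MED12, list means differed by 1.01 for interferon-stimulated genes (camera with an estimated correlation, adjusted p = 0.00198) and by -0.99 for heat shock genes (adjusted p = 0.00701). Between the shRNA arrays and the PQL/Opa-deleted construct they differed by 0.82 for interferon-stimulated genes (camera with an estimated correlation, adjusted p = 0.00439) and by -0.55 for heat shock genes (adjusted p = 0.0547).

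Interferon-stimulated genes were higher in the shRNA arrays. A narrow spread of values in some arrays is argued against as the whole cause: after cyclic loess, which removes each array's trend with the level of a row, the list mean was 1.21 where this explanation needs less than 0.6, and the shRNA array with the widest spread stood 1.36 above the highest GFP array. What stays open is whether the lower MED12 transcript, the hairpin RNA itself or its vector raised these genes, since 0 arms carry a control hairpin or an empty hairpin vector. The PQL/Opa-deleted arm, with more MED12 transcript and no hairpin, had a list mean of 0.37, so a rise of smaller size occurred without a hairpin or a lower MED12 row, but this does not decide for the shRNA arrays. A response to the double-stranded hairpin, to its vector or to the lower MED12 transcript may each account for the rise, and these cannot be told apart here.

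Heat shock genes were higher with full-length MED12. The narrow spread of some arrays is argued against as the whole cause, since after cyclic loess the list mean was 0.63 where this explanation needs less than 0.3, a gap wider than the 0.25 SD of the score in the GFP arrays. The mean of the list was lower with the PQL/Opa-deleted construct, but so was the MED12 row, by a log2 difference of 1.76 between the constructs. That difference may itself be partly one of sequence, since probes lying in the deleted domains would not read the shortened transcript, and where the probes lie is not given. The deleted domains and the amount of construct may each account for the difference between the constructs, and they cannot be told apart because the arms do not overlap in the MED12 row.

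Heat shock genes were lower in the shRNA arrays, with a list mean of -0.24 after cyclic loess and -0.31 without the 3 narrowest arrays; the call was lost with an estimated correlation (camera, adjusted p = 0.226). In both groups the score was lowest in the array whose values had the narrowest spread. It was -0.61, -0.31 and -0.04 in shRNA arrays with SDs of 1.34, 1.47 and 1.60. In GFP arrays with SDs of 1.40, 1.58 and 1.60 it was -0.28, 0.19 and 0.09, with no rise between the last 2. With that SD as a term in a linear model the difference from GFP was -0.21 ± 0.065 (SE) over the 12 arrays and -0.20 ± 0.052 (SE) over these 6, taking the slope as the same in each group. The bound set for spread as the whole cause was a mean above -0.15, and the 4 values lie below it. For the first 2 the gap is less than the 0.28 SD of the score between arrays. For the last 2 it is no more than their SE. In the linear model, however, spread as the whole cause would leave a difference near 0. Both of its values lie below 0 by several times their SE, with 7 and 3 residual degrees of freedom. If the slope is the same in each group, they argue against spread as the whole cause. A narrow spread may still account for part of the difference. The lower MED12 transcript, the opposite of the overexpression arm, stays open as a biological explanation and was not tested, for want of a control hairpin.

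Other splits of the same arrays were counted for each comparison. With 10 splits of 3 against 3 arrays a share under 0.05 cannot be reached. For full-length MED12 against GFP, 1 of the 10 splits gave as many rows (real 3, highest other 1) and 5 gave as many lists (real 6, highest other 10). For the PQL/Opa-deleted construct 2 of the 10 splits gave as many rows (real 1, highest other 1) and 5 as many lists (real 6, highest other 15). For the shRNA 2 of the 10 splits gave as many rows (real 15, highest other 183) and 5 as many lists (real 7, highest other 16). Between the constructs 1 of the 10 splits gave as many rows (real 1, highest other 0) and 5 as many lists (real 5, highest other 11). The split with 183 rows set shRNA replicates 1 and 3 and GFP replicate 1 against the other 3 arrays, which groups the 3 narrowest of these 6 arrays and points to a structure of the samples that the groups do not explain. For the F test 4 of 100 splits, the real one included, gave as many rows (real 19, highest other 584), a share under 0.05 by 1 split. The split with 584 rows points to a structure of the samples here too, so the count alone does not set the real groups apart from it.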

How the results depend on the processing

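Cyclic loess, the removal of the 3 narrowest arrays or of the 4 arrays numbered 1, and the counting of rows with several symbols were chosen only after the results were seen; the other alternatives were planned. Under alternatives the 15 main results had 348 values. Of these, 268 kept their direction and side of the threshold, or stayed within 1.5 times the count, and 80 did not. Why these 80 moved was not tested. Over 56 values of single genes, 1158 of 1283 alternatives were the same, 100 lost the call, 19 gained it and 6 turned the sign; over 6 further list means, 119 of 132 were the same and 13 lost the call. Interferon-stimulated genes stayed past the threshold with the shRNA in all 22 settings (means 1.08 to 1.31; 1.09 to 1.29 leaving out 1 array), as did heat shock genes with full-length MED12 (0.51 to 0.76; 0.53 to 0.76 leaving out 1 array) and interferon-stimulated genes with the PQL/Opa-deleted construct (0.33 to 0.42). Heat shock genes with the shRNA passed in 19 of 22. Over all groups, 9 of 12 arrays correlated best with an array of their own number and 13 of 18 same-numbered pairs exceeded 0.1. The same-numbered correlations were all above 0, from 0.022 to 0.472, with the highest median for number 1 (0.344). This points to something shared by arrays of a number. The labels do not name it, and the fit without a block leaves it in the spread. A block gave 4 rows for full-length MED12, 2 for the PQL/Opa-deleted construct and 18 for the shRNA, 14 of them among the 15, and changed no call for these constructs against GFP beyond those given with the results. With the shRNA it added IFIH1, SP110, RIGI and row 2328502 and left out OAS2 (1.45; limma, adjusted p = 0.0645), and among lists it added fibroblast markers (camera, adjusted p = 0.0494) and left out the HEK293 list (0.0509). Array weights gave 6, 20 and 5702 rows against GFP, 4 between the constructs and 5149 by the F test, and MED12 then fell by 0.81 with the shRNA (limma, adjusted p = 0.00190; in the other settings it did not pass). Quantile normalization gave 23 rows for the shRNA and 2 between the constructs, with 3 lists for the shRNA. Cyclic loess gave 5 rows for full-length MED12, 2 between the constructs and 4 lists for the shRNA. Without moderation there were 6 rows for the shRNA, 0 between the constructs and 3 by the F test. The shRNA count was 4 with only the compared groups and 4 without the arrays numbered 1. Between the constructs the count was 0 after median subtraction, with a trend, without the 3 narrow arrays and without those numbered 1, and 2 without dim rows or at a threshold of 0.1. The F test gave 8 rows without the narrow arrays and 6 without those numbered 1. MED12 no longer passed between the constructs after median subtraction (1.77; limma, adjusted p = 0.0568), with a trend (1.76; 0.0700), without moderation (1.76; 0.182), with only the compared groups (1.76; 0.116), without the narrow arrays (1.61; 0.0622) or those numbered 1 (1.63; 0.320). An estimated correlation left 1, 1 and 1 lists against GFP and 0 between the constructs; fry left 2, 2, 1 and 0. Without the narrow arrays 2 lists were called for the PQL/Opa-deleted construct and 10 between the constructs; without dim rows there were 3 for the shRNA. Leaving out each array in turn gave 3 to 4 rows for full-length MED12, 1 to 1 for the PQL/Opa-deleted construct, 5 (without GFP 2; 8 without GFP 3) to 20 (without shRNA 1) for the shRNA, 0 to 3 between the constructs, and 5 (without shRNA 3) to 18 by the F test. MED12 ranged from 1.61 to 1.92 between the constructs and lost its call in 9 of 12 fits. Lists ranged from 5 to 10 (without full-length 1), from 2 (without GFP 1 or PQL/Opa deletion 3; 3 without PQL/Opa deletion 2) to 12 (without GFP 3 or PQL/Opa deletion 1), from 1 (without shRNA 1; 2 without GFP 3, 3 without GFP 2) to 14 (without GFP 1 or shRNA 2), and from 4 to 9 (without PQL/Opa deletion 1) between the constructs. MED12L, near 0 throughout, turned from -0.07 to 0.014 with full-length MED12 without the narrow arrays and to 0.10 without those numbered 1 (-0.16 to 0.015 leaving out 1 array), and ranged from -0.19 to 0.13 with the shRNA. IFNB1, IFNE and IFNG lie among the dimmest rows, so their values do not show that they stayed at the control level.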

Other observations

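The comparison of the shRNA arrays with each MED12 construct, and the genes of interferon production and heat shock control named here, were chosen only after the results were seen; the 30 lists were fixed beforehand.

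Relative to GFP, the heat shock list score was highest with full-length MED12 (0.67) and lowest with the shRNA (-0.32). A narrow spread of values may account for part of the lower score with the shRNA. Between the shRNA arrays and the full-length MED12 arrays 23 rows differed, 10 higher and 13 lower with the shRNA (limma). DNAJB1 was 7.52-fold lower with the shRNA, a log2 difference of -2.91 (limma, adjusted p = 0.00400). HSPH1 was lower by a log2 difference of -2.12, HSPA1L by -1.87 and HSPA4L by -1.49, and these 4 list members passed over all rows, while 9 passed when adjusted over the list alone. DNAJB4, another co-chaperone, differed by -1.45 and ZFAND2A, a gene induced by heat and arsenite, by -1.76. Another 4 lower rows (2363784, 3391149, 2902725 and 2902707) are annotated to more than 1 gene, at least 1 of them in the heat shock list. Not all of them moved both ways from GFP. Row 3391149 had a log2 fold change of 0.23 with the shRNA, and row 2902707 had 0.10 with full-length MED12. SKP1 differed by -1.35. The 10 higher genes were TRIM22, RSAD2, IFI44, IFIT2, IFIT3, IFIT1, IFITM1, OAS2, NMI and SAMD9, with log2 differences from 1.18 to 2.27. Against the PQL/Opa-deleted construct 7 rows differed (limma). The higher ones were TRIM22 at 2.07, IFI44 at 1.58 and NMI at 1.28, and the lower ones were MED12, ZFAND2A at -1.51 and rows 2363784 and 2902725. The same limit holds for TRIM22 and NMI, whose means with this construct were 2.52 and 2.24.

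Among genes that encode interferons none passed with the shRNA. IFNB1, which encodes interferon beta, had 2.19 ± 0.13 (SD, n = 3) in the shRNA arrays against 2.14 ± 0.56 with GFP, and its mean of 2.04 lies at the 9.12th percentile of all rows. IFNE (5.25th percentile) had a log2 fold change of 0.06, IFNG (6.63th) 0.17 and IFNK (23.8th) -0.18. None of these rows is shown to be above background, so the values do not show that expression was unchanged. TLR3, a sensor of double-stranded RNA in endosomes, had 1.15 ± 0.28 (SE; limma, adjusted p = 0.553), ADAR, which edits double-stranded RNA, had 0.69, IRF3 0.35 and EIF2AK2, the kinase activated by double-stranded RNA, 0.29; none of these passed. HSF1, the main heat shock transcription factor, had -0.19 with full-length MED12 and -0.01 with the shRNA, and did not pass. UBB, whose promoter responds to heat shock, had 0.69 with full-length MED12 and 0.75 with the PQL/Opa-deleted construct and did not pass.

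Of the 30 lists, 18 were past the threshold in none of the 4 planned comparisons (camera), with adjusted p-values from 0.0614 upwards, mean log2 fold changes from -0.12 to 0.19 and 0 members past over all rows with limma. They were the other Mediator subunits, RNA polymerase II subunits, Wnt, Notch, TGF-beta and YAP, p53, NF-kB, endoplasmic reticulum stress, neuronal genes repressed by REST, neurodevelopmental transcription factors, DNA replication, cholesterol and fatty acid synthesis, the small RNA pathway, apoptosis regulators, and epithelial, fibroblast and blood cell markers. Markers of other cell types were not called in these comparisons without a block. With the shRNA, fibroblast markers had a mean of 0.15 with 14 of 15 above 0 (camera, adjusted p = 0.0614). Blood cell markers had 0.17 with 11 of 12 above 0 (camera, adjusted p = 0.122). The fibroblast scores of single arrays overlapped, from -0.03 to 0.34 with the shRNA and from -0.09 to 0.15 with GFP. So did the blood cell scores, from -0.04 to 0.34 with the shRNA and from -0.16 to 0.24 with GFP. Fibroblast markers were above 0 in 15 of 15 genes between the shRNA and full-length MED12, with a mean of 0.20 (camera, adjusted p = 0.0163; adjusted p = 0.497 with an estimated correlation).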
